A study of Mus musculus with 5 samples.

How the data were processed

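Poly(A) RNA was sequenced from lenses of 14-day-old (P14) mice in 5 libraries. The cKO group (conditional knockout of Yap1, which encodes a transcriptional co-activator of the Hippo pathway) had 2 libraries and the control group (Ctrl) had 3. Per the labels' protocols, each library was a pool of 4 to 6 whole lenses, and these pools are the biological replicates (n) in all tests. Per the labels' protocols, the cKO pools came from Yap1 f/f;Cre or f/+;Cre mice that were picked by a severe eye phenotype (small eyes and a closed pupillary membrane), and the controls were littermates with floxed alleles (f/f or f/+) and no abnormality, although the genotype field calls them WT. The Cre driver is not given in the sources used here. RNA had an integrity number above 8.0, 1 µg of it entered each library, and paired reads of 150 bp were made on a NovaSeq instrument, per the labels' protocols.

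The authors deposited 1 table with an estimated (expected) count and an FPKM value for 22183 mouse genes in each library, together with gene symbols and columns of Gene Ontology and KEGG pathway terms. The submitters' processing notes name RSEM, Trimmomatic 0.18.0 and the build GRCm39. The role of each tool, the aligner and the use of strand are not given in the sources used here. The deposited expected counts were not scaled between libraries, per the values. In a library, 6.03 to 7.47% of the values were not whole numbers. Such values mark reads shared with other genes, which may be near-identical copies. The deposited FPKM values, per the file headers, are scaled to gene length and library size by the authors, and served only as an alternative here. The reference annotation at hand is of another build, so no coordinates are given and all symbols are the file's own. Where symbols were shared by more than 1 identifier (20 symbols), the identifier with the highest total kept the symbol, and 13 genes without a symbol kept their identifier.

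Expected counts were rounded to whole numbers. Totals per library were 24320302 and 22672151 (cKO 1 and 2) and 24192565, 22047580 and 25762802 (Ctrl 1, 2 and 3). A count of 0 allows up to 3 counts in a library, which is 0.123 and 0.112 CPM (counts scaled to a common library size) in cKO 1 and 2 and 0.139, 0.146 and 0.115 CPM in Ctrl 1, 2 and 3. Where all libraries of a group had 0 counts, the fold was computed against 3 counts in each of its libraries and is a bound. Where a group had 1 to 3 counts in all, the ratio of the groups is given with its exact 95% interval. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

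Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), which left 11724 genes. Another 6422 of the 22183 genes had no count in any library. Libraries were scaled by TMM and cKO was compared with Ctrl by edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3), without a batch or block term. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Here "rose", "fell", "higher" and "lower" are used of called genes unless the text says otherwise. Standard errors (SE) of log2 fold changes were taken from the F statistic. The model had 3 residual and 3.26 prior degrees of freedom and a common dispersion of 0.128. Abundances are CPM after TMM scaling, as mean ± SD over the libraries of a group. Shares of counts were compared by an exact two-sided permutation test over the 10 ways to split 5 libraries into groups of 2 and 3, so that 0.1 is the smallest p it can give.

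Before the data were examined, 41 gene lists with 594 entries (589 genes, of which 585 are in the table) were fixed for lens cells, YAP and Hippo signalling, cell cycle, stress, matrix, metabolism, signalling, immune and vascular cells, and other tissues. Mx1, Rigi, Hprt1 and Ahsp are absent from the table. Each list was compared with all other tested genes by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists. Camera was repeated with an estimated correlation, and fry tested whether the genes of a list moved, on balance, one way. None of the camera calls held with an estimated correlation. Also fixed beforehand was the rule for naming genes. It names Yap1, the 10 called genes with the largest change each way among those with a mean CPM of at least 10, no overlap between groups and a regular gene symbol, up to 4 members of each list (the 2 most abundant and the 2 most changed called members, or the 2 most abundant tested ones where fewer passed), and the 16 crystallins. Genes named outside this rule are marked as chosen after their values were seen. Terms with 10 to 500 tested genes were compared with the called genes by Fisher's exact test against all 11724 tested genes, 3596 terms in each direction, with Benjamini-Hochberg adjustment. Fisher's test treats genes as independent, so its p-values can be too small where the genes of a term vary together.

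The test was tried on simulated counts made from the Ctrl means and the sizes of the 5 libraries. Of 11724 genes, 200 were changed, all above about 1 CPM. Each gene had the same dispersion in both groups, whereas the real cKO libraries differed more than the Ctrl ones. The rates below need not hold for such unequal spread. The test recovered 5 of 66 genes (7.58%) changed 2-fold, 35 of 67 (52.2%) changed 4-fold and 58 of 67 (86.6%) changed 8-fold. Of its 103 calls, 5 (4.85%) were false. A list of genes all raised 4-fold was called by camera and 0 of 20 random lists were. Counts were drawn independently for each gene. The trial therefore cannot show how often camera wrongly calls lists whose genes vary together. The alternatives tried were RLE, upper-quartile and total-count scaling, scaling without the 16 crystallins, DESeq2 1.42.0, limma-voom, robust dispersions, no count filter, a filter of 1 CPM in 2 libraries, a threshold of 0.01 or an added log2 change of 1, the replicate number as a block, limma on log2 FPKM with 1 or 0.1 added, and leaving out each library. A filter on a mean count of at least 100 was chosen after the data were seen. The share of crystallins was also computed from FPKM and without mitochondrially encoded genes. Figures were drawn with matplotlib 3.10.9.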

Results

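RNA was profiled in P14 lenses of Yap1 cKO mice and of control littermates, to find which transcripts differ in severely affected lenses. The 5 libraries held 22047580 to 25762802 expected counts each. Fewer genes had at least 1 count in the cKO libraries (12602 and 12028 in cKO 1 and 2) than in the Ctrl libraries (13972 to 14199; exact permutation test, two-sided p = 0.1). All pairs of Ctrl libraries had Pearson correlations of log2 CPM across genes of 0.962 to 0.978. The pair of cKO libraries was less alike, at 0.871, and pairs between the groups lay at 0.824 to 0.838. On principal components, the first (61.7% of variance) separated the groups and the second (28.1%) separated cKO 1 from cKO 2.

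Yap1 (ENSMUSG00000053110) was measured at 3.01 ± 1.05 CPM in cKO (n = 2) and 6.39 ± 0.855 CPM in Ctrl (n = 3). Its counts were 92 and 61 in cKO 1 and 2 and 155, 133 and 143 in Ctrl 1, 2 and 3, so that every cKO library lay below every Ctrl library. The log2 fold change was −1.08 (SE 0.33), which did not pass the threshold (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0759). Without Ctrl 1, 2 or 3 the change was −0.96, −1.07 and −1.14 and did not pass either (edgeR adjusted p = 0.256, 0.244 and 0.176). With only 1 cKO library left, it was −1.5 (without cKO 1) and −0.76 (without cKO 2). The count covers the whole gene and does not separate floxed exons from others.

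Of 11724 genes tested, 675 were higher and 906 were lower in cKO, 13.5% in all, and 437 of the higher and 784 of the lower genes changed at least 2-fold. At an unadjusted p under 0.05, edgeR gave 1737 higher and 2043 lower genes. Among the called genes, with fewer genes detected in cKO, 187 lower ones had 0 counts in both cKO libraries and 18 higher ones had 0 counts in every Ctrl library. These numbers are not like for like, since 0 in 2 libraries is easier to meet than 0 in 3. A gene seen in only 1 cKO library and in no Ctrl library also could not pass the count filter. Scaling by total counts alone shifted the median log2 fold change by 0.213 and gave 1234 higher and 717 lower genes, and log2 FPKM with 1 added shifted it by 0.193 and gave 1380 and 743. Leaving out Ctrl 1, 2 or 3 left 64, 21 and 80 of the 1581 calls. The calls numbered 1774 higher and 2845 lower without cKO 1 and 2197 and 2964 without cKO 2, where the lone cKO library is assumed to vary like the controls. The groups also differed in Y-linked transcripts (Ddx3y and Eif2s3y were at 0 in both cKO libraries). The cKO pools thus held almost no Y-linked RNA and each Ctrl pool did, so that sex was not separable from genotype in these libraries. The cKO lenses had also been picked by their phenotype.

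Crystallins took most of each library. The 16 crystallin genes held 67.76 ± 1.9% of counts in cKO and 72.61 ± 1.33% in Ctrl (exact permutation test, two-sided p = 0.1, the smallest that 10 splits allow). The γ class (Cryga to Crygf, Crygn and Crygs) took 16.02 ± 3.8% in cKO and 30.26 ± 0.33% in Ctrl, the largest difference of the classes, with no overlap of libraries (exact p = 0.1). The α class stood at 20.45 ± 3.27% in cKO and 15.6 ± 0.618% in Ctrl, and the β class at 31.27 ± 1.37% and 26.74 ± 0.693% (exact p = 0.1 for each).

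**Figure D1:**
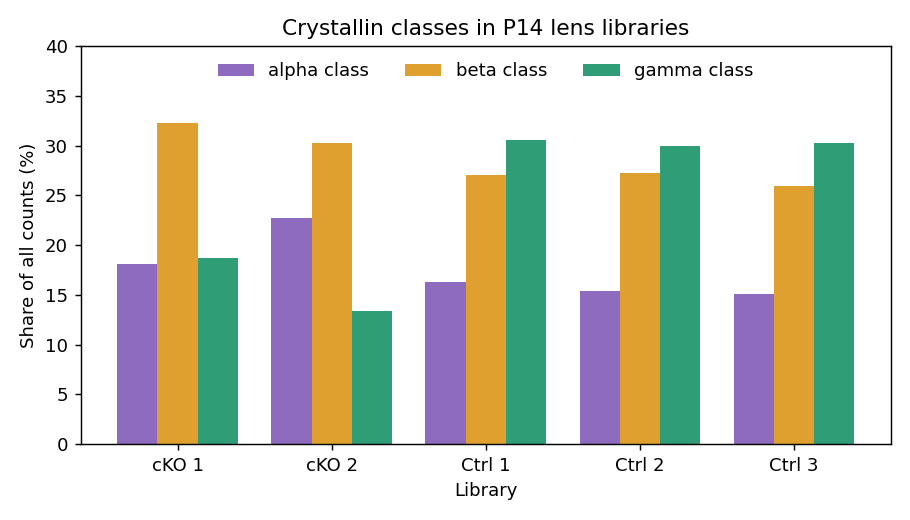
Share of all expected counts (%) taken by the α, β and γ crystallin classes in each of the 5 libraries (bars). The γ class took 18.71 and 13.34% in cKO 1 and 2 and 29.94 to 30.6% in the Ctrl libraries.

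Among single crystallins, Cryga fell by 4.14 on the log2 scale (SE 0.80, edgeR adjusted p = 0.0277), from 54534 ± 1834 CPM in Ctrl to 3084 ± 3175 CPM in cKO. Crygb fell by 1.43 (SE 0.34, edgeR adjusted p = 0.0448) and Crygc fell by 0.93 (SE 0.23, edgeR adjusted p = 0.0462). Crygd, Cryge and Crygf had negative changes of −0.49, −0.64 and −1.80 that did not pass (edgeR adjusted p = 0.141, 0.0646 and 0.0683). Counts of Cryga to Crygf were partly fractional, so reads were shared between near-identical copies and the split among them is uncertain. Cryaa (0.15), Cryab (0.24), Cryba1 (0.11), Crybb1 (0.27) and Crybb2 (0.03) did not pass. Adjusted over the list alone, 5 crystallins were lower and 0 higher, against 3 and 0 over all genes tested. The list's median log2 fold change of −0.21 was not called (camera adjusted p = 0.213) and moved to 0.00333 under total-count scaling, to 9.14e-07 with FPKM + 1 and to 1.48e-05 with FPKM + 0.1, and under total-count scaling 1 crystallin was called higher. Without cKO 1 the median was −0.43 and was called lower (camera adjusted p = 0.00284), and without cKO 2 it was −0.15 and was not (camera adjusted p = 0.262).

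Other fibre-cell genes moved both ways. Lgsn, which encodes the lens protein lengsin, fell by 4.20 (SE 0.67, edgeR adjusted p = 0.0188), from 2973 ± 556 to 162 ± 141 CPM. Caprin2 fell by 2.0 (SE 0.19, edgeR adjusted p = 0.00588) and Tdrd7, also an RNA-binding protein gene, by 0.83 (SE 0.14, edgeR adjusted p = 0.0207). The beaded-filament gene Bfsp1 fell by 1.34 (SE 0.24, edgeR adjusted p = 0.0227), from 4207 ± 89.3 to 1667 ± 565 CPM. Adjusted over the list alone, 6 of the 19 tested fibre genes were lower and 1 higher, against 4 and 1 over all genes tested. The higher gene was the transcription factor Maf (1.0, SE 0.17, edgeR adjusted p = 0.0212), named after its values were seen. The list's median of −0.63 was not called (camera adjusted p = 0.135), but was without cKO 1 (−0.34, camera adjusted p = 0.00173) and without Ctrl 1 (−0.60, camera adjusted p = 0.0445).

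The lens epithelium list was lower in cKO by its median, but not in its most abundant members. The median log2 fold change was −1.87 over 15 genes (camera adjusted p = 2.83e-08; adjusted p = 0.3 with an estimated correlation), and the call held with each of the 5 libraries left out. By fry, its genes moved down on balance (adjusted p = 0.0193). Adjusted over the list alone, 9 genes were lower and 0 higher, against 7 and 0 over all genes tested. Cdh1, which encodes E-cadherin, had 1 and 0 counts in cKO 1 and 2 and 440 to 986 in Ctrl, a ratio of 1500 (95% interval 268 to 59100; edgeR adjusted p = 0.00275). The gap-junction gene Gja1 fell by 5.52 (SE 0.41, edgeR adjusted p = 0.00352), from 50.6 ± 12.9 to 1.11 ± 0.513 CPM. Npnt fell by 2.18 (SE 0.24, edgeR adjusted p = 0.00756), and Mab21l2 was at 0 in cKO and at least 6.15-fold lower. Chosen after its values were seen, Pax6 fell by 1.87 (SE 0.18, edgeR adjusted p = 0.0063), from 36.3 ± 3.11 to 9.91 ± 1.58 CPM. The summed abundance of the list was 1380 CPM in cKO 1 and 2680 CPM in cKO 2, against 2210 to 2440 CPM in Ctrl, so that cKO 2 lay above every Ctrl library. Also chosen after its values were seen, Dkk3, the most abundant member, lay at 1396 ± 692 CPM in cKO and 1395 ± 112 CPM in Ctrl, a log2 fold change of 0.00 (SE 0.31, edgeR adjusted p = 0.999). The next most abundant members, Sfrp1, Itga6, Dapl1 and Mab21l1, likewise overlapped between the groups and did not pass (−0.25, 0.06, −0.43 and −0.19; edgeR adjusted p = 0.477 to 0.882).

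Cell-cycle transcripts were lower as a list, with a median of −2.0 over 27 genes (camera adjusted p = 1.07e-06; adjusted p = 0.492 with an estimated correlation), and this call held with each library left out. Adjusted over the list alone, 12 genes were lower and 0 higher, against 10 and 0 over all genes tested. The replication-licensing genes Mcm7 and Mcm6 fell by 1.5 (SE 0.33, edgeR adjusted p = 0.0354) and by 2.84 (SE 0.46, edgeR adjusted p = 0.0193). The mitotic kinase genes Plk1 and Bub1 were at 0 in cKO, at least 15.5-fold and 8.33-fold lower (edgeR adjusted p = 0.0163 and 0.0297). All of these were low in Ctrl too, where Mcm7 had 7.57 ± 1 CPM and Plk1 1.82 ± 0.45 CPM.

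**Figure D2:**
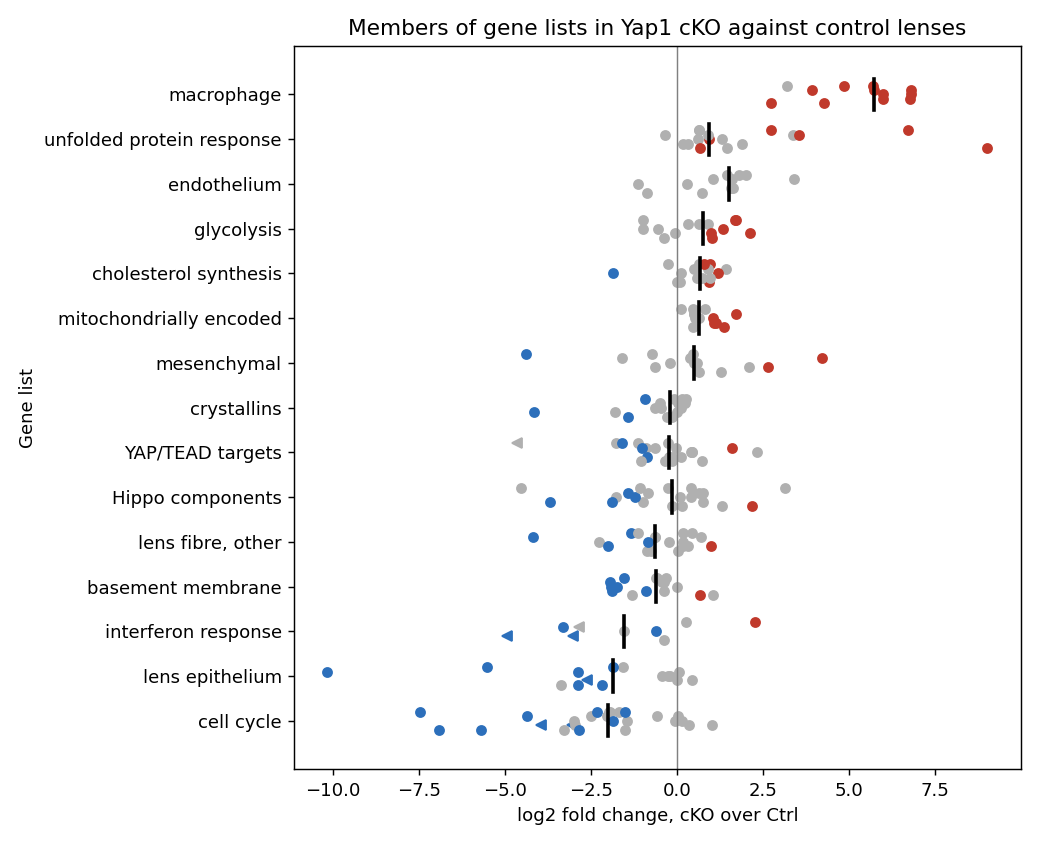
Log2 fold change (cKO over Ctrl, x axis) of each tested member of 15 gene lists (y axis), red for called higher, blue for called lower and grey for not called. Black lines are medians, which run from 5.72 (macrophage) to −2.0 (cell cycle), triangles are bounds for genes at 0 in a group, and fitted values of members with 1 to 3 counts in a group, such as Cdh1, depend on the prior count.

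Transcripts of the pathway itself changed in both directions. The 22 tested YAP and TEAD target genes had a median of −0.23 (camera adjusted p = 0.527), with 3 lower and 1 higher over all genes tested and 5 lower and 1 higher adjusted over the list alone. This median was −0.75 without cKO 1, −0.40 without cKO 2 and −0.03 under total-count scaling, and was not called in any of these (camera adjusted p = 0.561, 0.262 and 0.514). Ccdc80 fell by 1.59 (SE 0.29, edgeR adjusted p = 0.0244), Tgfb2 fell by 1.02 (SE 0.18, edgeR adjusted p = 0.0232) and Fjx1 rose by 1.6 (SE 0.39, edgeR adjusted p = 0.0451). Ccn1 and Ccn2, both widely used YAP targets chosen after their values were seen, had changes of −0.65 and 0.45 and did not pass (edgeR adjusted p = 0.585 and 0.157). Of 21 Hippo components, Frmd6 fell by 3.70 (SE 0.29, edgeR adjusted p = 0.00373), Mob1a fell by 1.43 (SE 0.24, edgeR adjusted p = 0.0212) and the YAP partner Tead1 rose by 2.18 (SE 0.32, edgeR adjusted p = 0.0148), from 1.47 ± 0.153 to 6.65 ± 1.66 CPM. The median of the Hippo list was −0.15 (camera adjusted p = 0.248) and changed sign under total-count scaling (0.14) and with FPKM + 1 (0.10) or FPKM + 0.1 (0.22). Over all genes tested 4 Hippo genes were lower and 1 higher, against 8 and 2 adjusted over the list alone.

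The unfolded-protein and integrated-stress list was higher, with a median of 0.92 over 17 genes (camera adjusted p = 4.44e-06; adjusted p = 0.663 with an estimated correlation). Adjusted over the list alone, 9 were higher and 0 lower, against 6 and 0 over all genes tested. Asparagine synthetase (Asns) rose by 2.73 (SE 0.32, edgeR adjusted p = 0.00957), from 14.4 ± 0.412 to 95.3 ± 50.6 CPM, and the chaperone gene Hsp90b1 by 0.68 (SE 0.13, edgeR adjusted p = 0.0281). Chac1 rose by 9.03 (SE 0.98, edgeR adjusted p = 0.00756) and Trib3 by 6.73 (SE 1.38, edgeR adjusted p = 0.0307), each with far more counts in cKO 1 (1981 and 2205) than in cKO 2 (444 and 95). Outside the list and chosen after its values were seen, the integrated-stress gene Ppp1r15a went the other way, falling by 3.52 (SE 0.52, edgeR adjusted p = 0.015) from 582 ± 24.4 to 50.7 ± 37.8 CPM. Gdf15 rose by 5.73 (SE 0.74, edgeR adjusted p = 0.012). Gdf15 belongs to the p53 and apoptosis list, whose median of 0.67 was not called (camera adjusted p = 0.261), with 2 higher and 4 lower over all genes tested and 6 and 4 adjusted over the list alone. There Perp rose by 1.37 (SE 0.20, edgeR adjusted p = 0.0153) and Fas fell by 1.92 (SE 0.45, edgeR adjusted p = 0.0428). Heat-shock genes were not called in either direction (median −0.06, camera adjusted p = 0.979).

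**Figure D3:**
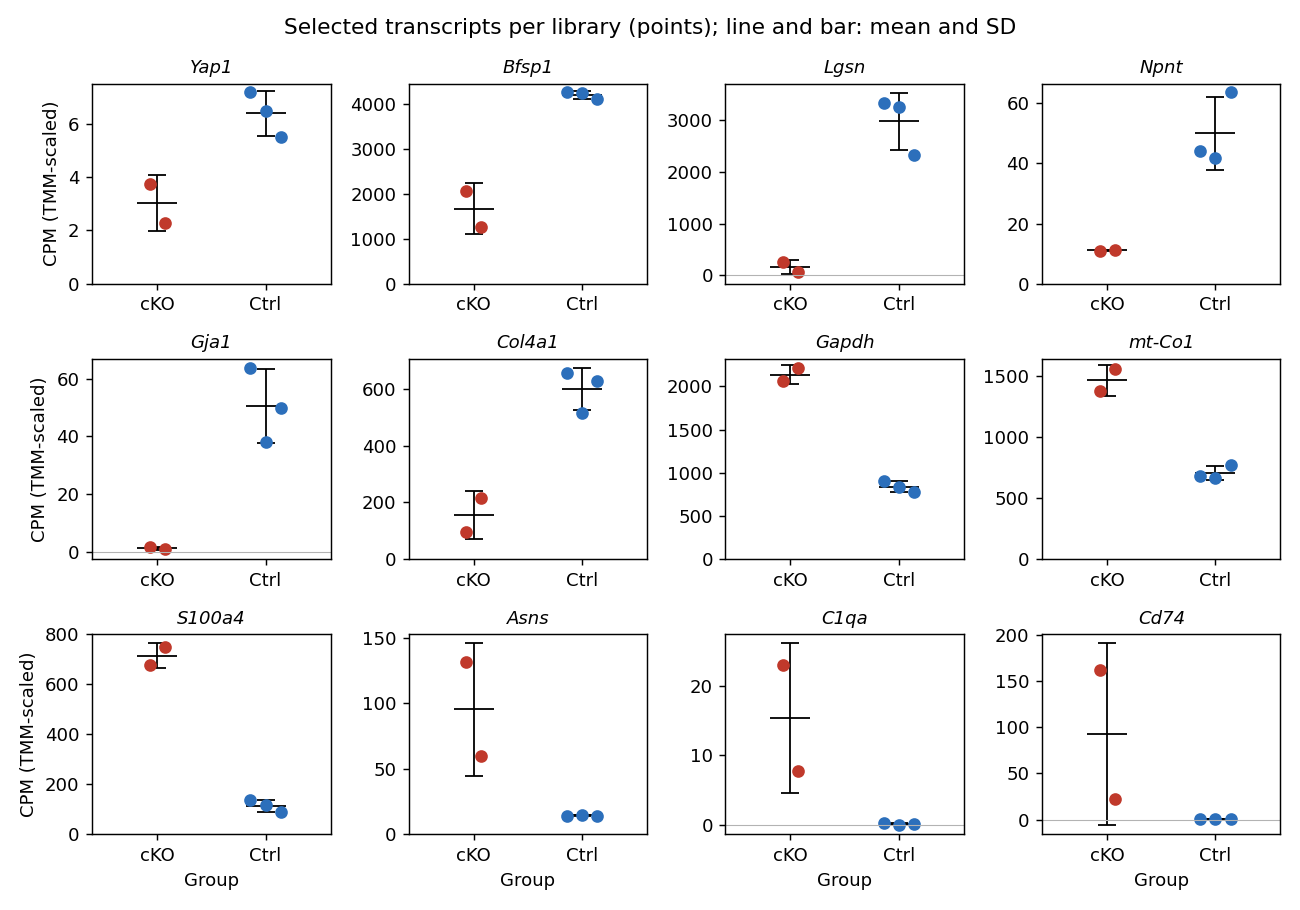
TMM-scaled CPM (y axis, linear) of 12 transcripts in the cKO (n = 2) and Ctrl (n = 3) libraries (points), with the mean (line) and SD (bar). The groups do not overlap for any of the 12. All but Yap1 were called, and 0 of the 1581 called genes had overlapping groups, so this does not set them apart. Cd74 and C1qa differ widely between the cKO libraries (3958 and 610 counts, 561 and 207 counts).

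Glycolytic transcripts were higher, with a median of 0.77 over 14 genes (camera adjusted p = 9.43e-05; adjusted p = 0.506 with an estimated correlation). Adjusted over the list alone, 8 were higher and 3 lower, against 6 and 0 over all genes tested. Aldoa rose by 1.72 (SE 0.16, edgeR adjusted p = 0.00555), from 304 ± 36.3 to 1003 ± 86.8 CPM, and Gpi1 by 2.12 (SE 0.23, edgeR adjusted p = 0.00756). Gapdh, which shares reads with near-identical copies, rose by 1.35 (SE 0.14, edgeR adjusted p = 0.00727). Mitochondrially encoded transcripts took 0.625 ± 0.0651% of counts in cKO and 0.299 ± 0.0476% in Ctrl (exact permutation p = 0.1). All 13 had positive changes, with a median of 0.64 (camera adjusted p = 1.07e-06; adjusted p = 0.506 with an estimated correlation). Of these, 5 were higher over all genes tested and 8 adjusted over the list alone, among them mt-Co1 (1.06, SE 0.15, edgeR adjusted p = 0.014) and mt-Nd1 (1.73, SE 0.17, edgeR adjusted p = 0.00689). The cholesterol-synthesis list was higher (median 0.68, camera adjusted p = 0.00818; adjusted p = 0.663 with an estimated correlation), with 4 higher and 1 lower over all genes tested and 8 and 1 adjusted over the list alone, but was not called without cKO 2 (0.48, camera adjusted p = 0.275). Idi1 rose by 1.21 (SE 0.27, edgeR adjusted p = 0.0391) and Fdps by 0.95 (SE 0.15, edgeR adjusted p = 0.0172), whereas Dhcr7 fell by 1.85 (SE 0.26, edgeR adjusted p = 0.014). Glutathione and antioxidant genes were not called as a list (median −0.48, camera adjusted p = 0.527). Over all genes tested 1 was higher and 2 lower, against 4 and 5 adjusted over the list alone. Of these, Gstm1 fell by 1.92 (SE 0.27, edgeR adjusted p = 0.0137) and Gclm rose by 0.61 (SE 0.15, edgeR adjusted p = 0.0487).

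Lysosomal, proton-transport and iron-handling terms led the enrichments among higher genes, where 54 of 3596 terms passed (309 at an unadjusted p under 0.05). The test took genes as independent and used only the calls from the full set of libraries. Terms also shared genes and are not separate results. Atp6v0c, for example, counts in the lysosome pathway, in proton transmembrane transport and in the vacuolar proton pump complex. The lysosome pathway had 30 higher genes of 119 tested, against 6.85 by chance (Fisher's exact test, adjusted p = 1.2e-08), among them Ctsd but also Ctss and Laptm5 of the macrophage list, and the lysosome component (50 of 336, 19.3 by chance, Fisher adjusted p = 5.51e-07) included Cd74 and H2-Aa. Macrophage transcripts were higher in the same cKO libraries, so the part of these terms that comes from macrophages was not separated. Proton transmembrane transport, next in rank after the lysosome pathway, had 20 of 65 (3.74 by chance, Fisher adjusted p = 5.32e-07), among them proton-pump genes but also mt-Co1, mt-Co2 and mt-Co3. The vacuolar proton pump complex had 7 of 13 (0.748 by chance, Fisher adjusted p = 0.00104), ferroptosis 12 of 35 (2.02 by chance, Fisher adjusted p = 0.000177) and iron ion transport 9 of 17 (0.979 by chance, Fisher adjusted p = 9.5e-05). Chosen after their values were seen as abundant called genes, Ctsd rose by 1.73 (SE 0.14, edgeR adjusted p = 0.00373) and the ferritin genes Fth1 and Ftl1 by 0.82 (SE 0.16, edgeR adjusted p = 0.0288) and 1.41 (SE 0.20, edgeR adjusted p = 0.0137). Ftl1 shares reads with a near-identical copy, which itself counts in the iron and ferroptosis terms. Among lower genes 2 terms passed (225 at an unadjusted p under 0.05), namely integral component of plasma membrane, with 60 of 425 (32.8 by chance, Fisher adjusted p = 0.0117), and basement membrane, with 18 of 74 (5.72 by chance, Fisher adjusted p = 0.0169).

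The fixed basement-membrane list was lower too, with a median of −0.60 over 16 genes (camera adjusted p = 0.00818; adjusted p = 0.678 with an estimated correlation), a call that was lost without cKO 1 (−0.17, camera adjusted p = 0.467). It held 6 lower and 1 higher gene, both over all genes tested and adjusted over the list alone. Col4a1 fell by 1.96 (SE 0.36, edgeR adjusted p = 0.0252), from 601 ± 75.2 to 155 ± 83.5 CPM, Lamc1 by 1.91 (SE 0.18, edgeR adjusted p = 0.00558) and Nid1 by 0.91 (SE 0.18, edgeR adjusted p = 0.0296). Interstitial-matrix genes were not called as a list (camera adjusted p = 0.828). Over all genes tested 1 was higher and 1 lower, against 1 and 2 adjusted over the list alone. Col1a1 rose by 4.44 (SE 0.86, edgeR adjusted p = 0.0275), from 0.169 ± 0.178 to 3.71 ± 1.44 CPM, and Loxl1 fell by 1.65 (SE 0.24, edgeR adjusted p = 0.0145). In the mesenchymal list (median 0.48, camera adjusted p = 0.077, and 0.0193 without Ctrl 1; 2 higher and 1 lower in both ways of adjusting), S100a4 rose by 2.66 (SE 0.20, edgeR adjusted p = 0.00373), from 113 ± 23 to 715 ± 51 CPM with partly shared reads, and Postn by 4.23 (SE 0.60, edgeR adjusted p = 0.0145). Pdgfra fell by 4.38 (SE 1.08, edgeR adjusted p = 0.047), with 48 and 0 counts in cKO 1 and 2. Of the TGF-β and BMP list, 3 genes were higher and 2 lower over all genes tested, against 4 and 3 adjusted over the list alone. Id2, Id1 and Bmp7 rose by 1.16, 1.04 and 1.17 (SE 0.13, 0.23 and 0.18, edgeR adjusted p = 0.008, 0.0386 and 0.017), whereas Id3 fell by 1.25 (SE 0.28, edgeR adjusted p = 0.0391). The list itself was not called (camera adjusted p = 0.527), with a median of −0.13 but a mean of 0.07. The ERK feedback genes Dusp6 and Spry4 rose by 1.68 and 3.89 (SE 0.41 and 0.68, edgeR adjusted p = 0.0475 and 0.0223). They were the 2 higher genes of the FGF and ERK list over all genes tested, against 4 adjusted over the list alone, with 0 lower in both. Of the Notch and Wnt list 0 were higher and 2 lower in both ways of adjusting. Notch2 fell by 4.30 (SE 0.62, edgeR adjusted p = 0.0147).

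Macrophage transcripts had the largest positive median of the lists tested. It was 5.72 over 12 genes (camera adjusted p = 1.4e-12; adjusted p = 0.492 with an estimated correlation). Of these genes, 11 were higher over all genes tested and 12 adjusted over the list alone. The camera call held with each library left out (median 3.83 over 12 genes without cKO 1 and 6.40 over 18 without cKO 2). Another 8 of the 20 listed genes did not pass the count filter, and without a filter the median over all 20 was 5.56 (camera adjusted p = 6.81e-15). The fry test did not pass (adjusted p = 0.0789). C1qa rose by 6.80 (SE 0.85, edgeR adjusted p = 0.0111), C1qc by 6.77 (SE 0.89, edgeR adjusted p = 0.0125) and Ctss by 6.82 (SE 1.15, edgeR adjusted p = 0.021). The summed abundance of all 20 listed genes was 225 CPM in cKO 1 and 48.2 CPM in cKO 2, against 2.20 to 4.78 CPM in Ctrl. Cd74, which encodes the invariant chain of MHC class II, rose by 7.22 (SE 1.00, edgeR adjusted p = 0.0137). The term for antigen presentation by MHC class II had 6 of 12 genes higher (0.691 by chance, Fisher adjusted p = 0.00488). Retnla had 17817 and 2549 counts in cKO 1 and 2 and 2 counts over all Ctrl libraries, a ratio of 13500 (95% interval 3740 to 112000; edgeR adjusted p = 0.00647). Chil3, which shares reads with near-identical copies, was at 0 in Ctrl and had 9031 and 923 counts in cKO 1 and 2 (edgeR adjusted p = 0.0263), at least 1509-fold higher by the cKO mean and at least 257-fold by cKO 2 alone.

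The interferon-response list moved the other way, with a median of −1.55 over 9 genes (camera adjusted p = 0.0274; adjusted p = 0.492 with an estimated correlation), and was not called without cKO 1 or cKO 2 (camera adjusted p = 0.257 and 0.131). Over all genes tested 4 were lower and 1 higher, against 5 and 1 adjusted over the list alone. Rsad2 fell by 3.32 (SE 0.58, edgeR adjusted p = 0.0223) and Usp18 was at 0 in cKO, at least 30.9-fold lower (edgeR adjusted p = 0.00917). The higher gene was Bst2 (2.28, SE 0.56, edgeR adjusted p = 0.0468), named after its values were seen. Endothelial genes had a median of 1.51 (camera adjusted p = 0.0354; adjusted p = 0.663 with an estimated correlation), but none of the 12 was called by edgeR, over all genes tested or adjusted over the list alone. The list was not called without cKO 1 (camera adjusted p = 0.405), cKO 2 (0.0912) or Ctrl 2 (0.0746). Immediate-early genes had a median of 1.80 (camera adjusted p = 0.0354; adjusted p = 0.663 with an estimated correlation), likewise with 0 of 9 called in both ways. They were not called as a list without cKO 1 (camera adjusted p = 0.426) or Ctrl 1 (0.0713). Inflammatory mediators (median −1.05, camera adjusted p = 0.825) and erythroid genes (median 0.63, camera adjusted p = 0.87) were not called. Hbb-bs and Hba-a1 had log2 fold changes of 0.47 and 0.79 that did not pass (edgeR adjusted p = 0.844 and 0.751). Without cKO 1 they were called lower (−3.98 and −5.08, edgeR adjusted p = 0.036 and 0.023).

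Lists of neighbouring tissues and further pathways were also compared. Of 14 corneal and conjunctival genes only 3 could be tested, and all 3 were lower in both ways of adjusting. As a list they were lower too (camera adjusted p = 0.000389, and 0.492 with an estimated correlation). Their median was −4.19 when genes at 0 are set to their bound. Aldh3a1 and Krt4 were at 0 in cKO and at 5.72 ± 3.06 and 2.14 ± 0.504 CPM in Ctrl. Without cKO 2 this list was not called (camera adjusted p = 0.0912). Pigment-cell genes had a median of −3.86 over 4 genes (camera adjusted p = 0.0274; adjusted p = 0.492 with an estimated correlation), with 0 called over all genes tested and 4 lower adjusted over the list alone, and were not called without cKO 2 (camera adjusted p = 0.327) or Ctrl 3 (0.0853). Photoreceptor genes were not called as a list (median −1.41, camera adjusted p = 0.828). The cone arrestin gene Arr3 had 2 counts in Ctrl and 80 and 32 in cKO 1 and 2, a ratio of 74.3 (95% interval 20.1 to 621; edgeR adjusted p = 0.0307). Lists for complement, Notch and Wnt, FGF and ERK, polarity and junctions, housekeeping, lymphocytes, neutrophils, pericytes, pigment epithelium, inner retina, ciliary body, skeletal and smooth muscle and Schwann cells were not called (camera adjusted p = 0.215 to 0.987), and no periocular mesenchyme gene could be tested.

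The remaining genes named by size of change were mostly low in 1 group. Among lower genes, Podn fell by 5.30 (SE 0.40, edgeR adjusted p = 0.00373) and kept its call with each library left out, as did Cdh1, Gja1, Ddx3y and Eif2s3y, which together are 5 of the 90 called genes that the naming rule covers. Sulf1 (−7.19), Dhx57 (−6.67), St8sia2 (−5.78), S1pr3 (−5.54) and Gstm2 (−5.42) were also lower, with SE of 0.47 to 1.11 and edgeR adjusted p = 0.00315 to 0.0296. Sulf1, St8sia2, S1pr3 and Gstm2 had 9, 15, 71 and 52 counts in cKO 1 but 0, 0, 0 and 1 in cKO 2. The size of their changes is therefore uncertain. Without cKO 2 the changes were −6.157, −4.748, −4.515 and −4.419. Without cKO 1 the fitted values ran from −13.63 to −10.08, but at 0 or 1 counts they depend on the prior count and are not measured sizes. Each of these 4 lost its call without Ctrl 1, Ctrl 2 or Ctrl 3. Dhx57 had 7 and 2 counts in cKO 1 and 2 and lost its call without Ctrl 2 (edgeR adjusted p = 0.055). Among higher genes were Nmrk2 (6.54), St8sia5 (6.21) and Slc7a3 (6.20), with 3154, 1450 and 1373 counts in cKO 1 and 896, 104 and 139 in cKO 2 (SE 0.66, 1.26 and 1.04, edgeR adjusted p = 0.00699, 0.0303 and 0.021). Each of them lost its call without Ctrl 1, Ctrl 2 or Ctrl 3, as did every other higher gene named by size of change.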

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

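All alternatives here were planned before the data were examined except the filter on a mean count of at least 100, which was chosen after seeing the data and gave 559 higher and 647 lower genes. Against 675 higher and 906 lower genes, RLE, upper-quartile and crystallin-free scaling, limma-voom, robust dispersions, no filter and the 1 CPM filter gave 595 to 729 higher and 786 to 930 lower genes. Total-count scaling gave 1234 higher genes, log2 FPKM with 1 or 0.1 added gave 1380 and 1402, and DESeq2 gave 1209 higher and 1521 lower genes. On the simulated counts, with equal dispersion in both groups, DESeq2 made 132 true and 51 false calls where edgeR made 98 and 5. An adjusted p under 0.01 left 57 and 93 genes, and a log2 change of at least 1 left 437 higher genes. With each library left out in turn, higher genes numbered 6 to 2197 and lower genes 15 to 2964. The lowest numbers came without a Ctrl library, and the highest without a cKO library, where the lone cKO library is assumed to vary like the controls. Both leave the same number of samples, so sample number alone does not explain the difference. No called gene changed sign in these settings except 3 in each FPKM setting. The replicate numbers are not stated to pair the samples. Deviations of the same-numbered libraries correlated at 0.111 and −0.083. With 2 cKO libraries these deviations mirror each other (−0.111 for cKO 2 with Ctrl 1), so they cannot decide on pairing. The fit with a replicate block gave 68 higher and 107 lower genes. Under this replicate block, the crystallin median became −0.28 (camera adjusted p = 0.0424) and the fibre median −0.45 (0.0424), both called, as was the photoreceptor median (−2.28, 0.0231). The Yap1 change was −1.07 with DESeq2 (adjusted p = 0.0392) and −1.50 to −0.76 with a library left out, called without cKO 1 and without cKO 2. The fibre median was −0.61 with DESeq2 (adjusted p = 0.0301) and −0.60 to −0.29 with a library left out, and the crystallin median −0.43 to −0.13, called without cKO 1 (adjusted p = 0.00284). The YAP and TEAD target median, called in none of the settings, ran from −0.75 to −0.17 with a library left out and was −0.62 with the block and −0.03 with total counts. The epithelial median of −1.87 and the macrophage median of 5.72 lost their call with an estimated correlation (adjusted p = 0.3 and 0.492), and the macrophage median also with fry (0.0789). With an estimated correlation so did the medians of cell cycle (−2.0), basement membrane (−0.60), interferon (−1.55), unfolded protein (0.92), cholesterol (0.68), glycolysis (0.77), mitochondrial (0.64), immediate-early (1.80), endothelial (1.51), pigment (−3.86) and corneal genes (fitted −8.68), at adjusted p = 0.492 to 0.678. With fry the basement-membrane (−0.60), unfolded-protein (0.92), cholesterol (0.68), immediate-early (1.80) and endothelial (1.51) medians did (0.12 to 0.209), while the Hippo median (−0.15) was called (0.0329). Endothelial and immediate-early medians were uncalled with total counts (1.68 and 1.90), DESeq2 (1.54 and 1.81) and FPKM + 1 (0.42 and 1.44), the immediate-early one with FPKM + 0.1 (1.72), and the endothelial one without a filter (1.26) and with the 1 CPM filter (1.27). The interferon median was uncalled with limma-voom (−1.94), the 1 CPM filter (−1.54) and FPKM + 1 (−0.33), and the pigment median with limma-voom (−4.47), no filter (−1.08) and the 1 CPM filter (−4.21). The mesenchymal median was called with DESeq2 (0.50), no filter (0.59) and the 1 CPM filter (0.50), and skeletal muscle without a filter (4.99). With a library left out, medians that changed call ran from 0.29 to 0.58 (mesenchymal), −1.30 to −0.17 (basement membrane) and −2.67 to −0.84 (interferon). Others ran from 0.48 to 0.85 (cholesterol), 0.69 to 2.92 (immediate-early), 1.02 to 1.70 (endothelial), −6.0 to −3.22 (pigment) and −0.56 to 7.17 (skeletal muscle). The corneal median ran from −8.91 to −7.15, but these values were fitted to genes at 0 in cKO and depend on the prior count. Without cKO 1, Hbb-bs and Hba-a1 went from uncalled positive changes to called negative ones (−3.98 and −5.08), and over the leave-one-out fits they ran up to 1.49 and 1.79. Except where a setting applies a stricter threshold, the cause was not tested. Depth limits the low genes, since crystallins held 66.41 to 73.94% of the 22047580 to 25762802 counts per library.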

Other observations

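All tests in this part were chosen only after the result was seen, except the one on genes of at least 100 CPM, which was fixed before its value was known.

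Y-linked transcripts separated the groups. Ddx3y had 656 to 854 counts and Eif2s3y 558 to 772 counts in the Ctrl libraries and 0 in both cKO libraries, and Kdm5d was at 0 in cKO too, while Uty had 2 and 0 counts. Loss through low library complexity is argued against, since only 0.633% of other genes at like levels in Ctrl (46 of 7263) had at most 2 counts in both cKO libraries, although the cKO libraries did detect fewer genes in all (12602 and 12028 with at least 1 count, against 13972 to 14199 in Ctrl). The X-linked partners decided nothing, with a median log2 change of 0.241, where Eif2s3x rose by 0.57 (edgeR adjusted p = 0.0404) and Ddx3x, Kdm5c and Kdm6a did not pass. The sex of the pooled mice is not given in the sources used here. The Y-linked counts show almost no RNA from male lenses in the cKO pools and some in each Ctrl pool. The near absence of these transcripts is the observation itself, and no further test of sex was made. Effects of sex and of Yap1 loss therefore cannot be told apart in the other genes, because the design confounds them.

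The cKO libraries disagreed at genes with 0 counts. Between cKO 1 and 2, 92 genes had 0 counts in one and at least 50 in the other, against 1, 12 and 14 genes in the Ctrl pairs. Lower depth is argued against, since counts outside the crystallins were 1.15 times as high in cKO as in Ctrl. A different share of only 1 cell type is argued against too, since it would put the zeros on one side. Instead, 42.4% of the genes (39 of 92) lay in the less frequent direction. Differing shares of several cell types could put zeros on both sides and were not tested. Summed macrophage genes were higher in cKO 1 (225 and 48.2 CPM in cKO 1 and 2) and epithelial genes in cKO 2 (1380 and 2680 CPM). The epithelial sum rests mostly on its most abundant member, Dkk3, and need not measure the share of epithelial cells. The called members Gja1 (1.47 and 0.745 CPM in cKO 1 and 2) and Npnt (11.0 and 11.1 CPM) did not follow it. Few RNA molecules behind the cKO libraries could not be told apart from differing pools. At genes of at least 100 CPM the cKO libraries still differed 2.17 times as much as the most different Ctrl pair (median absolute log2 ratio 0.313 against 0.144), a value between those set for either answer. This excess was 2.4 at 1 to 10 CPM and 2.35 at 10 to 100 CPM. The ratio itself fell with abundance in both groups. From low to high abundance it was 0.723, 0.383 and 0.313 in the cKO pair. In the most different Ctrl pair it was 0.301, 0.163 and 0.144. A steady excess therefore does not decide about few molecules. The smaller number of genes detected in cKO does not decide either, since differing shares of several cell types could also lower it. Genes with at least 10 counts numbered 10979 and 10723 in cKO 1 and 2 and 11130 to 11343 in Ctrl. Per the labels' protocols, 1 µg of RNA entered each library. Differences in severity or genotype between the pooled lenses stay open and were not tested.

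Macrophage transcripts were higher in both cKO libraries, 65.2-fold in cKO 1 and 14-fold in cKO 2 as a sum of all 20 listed genes over the Ctrl mean. A single odd library is argued against, since even in cKO 2 this sum was 10.1 times that of the highest Ctrl library, where the Ctrl libraries differed by at most 2.18 times, and 19 and 17 of the 20 genes lay above every Ctrl library in cKO 1 and 2. Blood is argued against too, since the haemoglobin sum was 2.62-fold in cKO 1 and 0.0886-fold in cKO 2, at most 0.0401 of the macrophage fold. For more attached vessels, the endothelial sum was 1.85-fold and 1.47-fold, at most 0.105 of the macrophage fold. The bound set against this was 0.1, so the test did not decide. Vessels with the Ctrl ratio of macrophage to endothelial transcripts would raise both sums alike. The values argue against such vessels as the whole source of the macrophage transcripts, while a part from vessels stays open. A candidate explanation that also stays open is macrophages in or on the severely affected lenses, for which no test beyond these values was made.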
